A study of Mus musculus with 14 samples.

How the data were processed

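Small RNA was sequenced from 14 tissues of C57BL/6J mice, a common inbred laboratory strain, with 1 library of pooled total RNA per tissue. Per the labels' protocols, tissues were harvested from mice, total RNA was extracted with Trizol, RNA of several animals was pooled, and libraries followed the standard Illumina procedure. The labels give 5 mice for the harvest and 10 mice for the pool, and which number holds was not settled here. The values are whole-number read counts per mature miRNA name, as deposited by the authors, with no scaling applied to them. The read trimming, the aligner, the miRNA reference release and the genome build are not given in the sources used here. How reads that match several near-identical miRNAs were counted is not given either, so members of the let-7 family, miR-10a and miR-10b, miR-133a and miR-133b, and miR-192 and miR-215 may share reads. Because no build is named, no coordinates are printed, and the RefSeq annotation of GRCm38.p6 served only to see which miRNA genes neighbour each other.

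The table lists 1046 names, of which 805 had at least 1 read in some library and 241 had none. Names follow an older convention, in which a star marks the arm of the hairpin taken as the less abundant arm, and 331 names carry a star. All 14 value columns were matched to a tissue by their names. Total counts per library ran from 622132 in pancreas to 9341000 in small intestine. At 100 RPM the smallest library holds 62 reads, which gives an exact Poisson interval of 76.4 to 128 RPM at 95% confidence. A count of 0 allows up to 3 reads, which is 0.321 RPM in the deepest library and 4.82 RPM in the shallowest.

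Counts were divided by the miRNA total of their library and multiplied by 1000000, giving RPM. Shares have exact Clopper-Pearson binomial intervals, RPM values have exact Poisson intervals, and folds between libraries have exact conditional binomial intervals, all at 95%. Reads carry no molecular identifiers here, so these intervals cover counting error only. With 1 library per tissue there are no replicates, no test between tissues was run, and fixed rules of size took its place. Every difference described compares these libraries, and none has a replicate check.

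A miRNA was counted as detected at 10 RPM. It was called tissue-enriched where its highest library had at least 100 RPM and at least 5 times the second highest, with 1 RPM added to both. The specificity index tau, which runs from 0 for even abundance to 1 for presence in a single tissue, was computed on log2(RPM + 1) for names at 10 RPM or more in some library, and 0.85 or more was called specific. For pairs of tissues, a name was counted with at least a 4-fold difference and at least 100 RPM in the higher library. The 20 miRNA lists (170 members, of which 1 had no matching name) covered striated muscle, neural tissue, hepatocytes, pancreas, white and red blood cells, the miR-200 family, squamous and intestinal epithelium, smooth muscle, endothelium, kidney, Hox clusters, multiciliated cells, gonads, the miR-183 cluster, the Dlk1-Dio3 cluster, the let-7 family, the miR-17~92 clusters and pluripotency. For each list and library, the median over members of log2(RPM + 1) minus the median of the other 13 libraries was set against 10000 random lists of the same size, matched on mean abundance in 10 bins. Profiles were compared by Spearman's rho across names at 10 RPM or more in any library, for all 91 pairs. Arms of a hairpin were compared where their sum reached 100 RPM in at least 2 libraries.

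The lists, rules and most alternatives were fixed before the data were examined. All list members could be named, together with the 3 most abundant miRNAs of each tissue, up to 4 tissue-enriched miRNAs per tissue with the largest ratio to the second tissue, up to 10 names per direction of a pair with the largest folds, and the 6 hairpins with the widest range of arm ratio. Alternatives were median-of-ratios size factors, totals without the 5 most abundant miRNAs of each library, a pseudocount of 10 RPM, other minimum levels and folds, names with identical values counted once, a profile comparison by Pearson's r, and leaving out cerebellum. Totals without miR-143, and runs without the libraries labelled colon and uterus or without those labelled colon, ovary and pancreas, were added after the data were seen. Compared with totals, median-of-ratios factors moved all values of a library on the log2 scale by 4.21 in the library labelled colon, 2.95 in ovary, 1.63 in pancreas and −1.75 in kidney. Leaving miR-143 out of the total moved the colon library by 6.27 and the ovary library by 2.96.

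For the comparison of reads other than miR-143, libraries were thinned to 86545 such reads in 20 random draws. GC content was taken from the hairpin transcripts of GENCODE M21, matched by gene name, for 339 of the 347 names at 10 RPM or more in brain or cerebellum. The rule for tissue-enriched names was tested on simulated counts for the 805 names. It called 37 of 37 names simulated at 10-fold and 45 of 45 at 20-fold, 0 of 34 at 5-fold, which lies on the rule's boundary, and no unchanged name. The simulated libraries shared a single profile and had counting error only. The lack of false calls therefore says nothing about differences in preparation or scaling between the real libraries. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.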

Results

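The series profiled miRNAs in brain, cerebellum, heart, lung, oesophagus, stomach, small intestine, colon, liver, pancreas, kidney, spleen, ovary and uterus of C57BL/6J mice, to describe which miRNAs each tissue holds. Each tissue was represented by 1 pooled library, so there are no replicates, and the values below carry counting error only. The libraries held 622132 counts in pancreas, 1134677 in cerebellum, 2267218 in ovary and between 4854014 (spleen) and 9341000 (small intestine) in the other tissues. At 10 RPM or more, brain held 319 names, cerebellum 274, oesophagus 226 and kidney 217. The library labelled colon held 57, ovary 82 and pancreas 105, and the median over the 14 libraries was 183.5. The libraries labelled colon and uterus are named by their labels throughout, because the intestinal miRNAs described below stood high in the second and low in the first.

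A few miRNAs made up most reads of every library. miR-122, the hepatocyte miRNA, held 43.7% of the liver reads (95% exact binomial interval 43.7–43.8%). In pancreas, miR-148a held 62.6% (62.4–62.7%). In heart, miR-378 held 35.6% and miR-1, a miRNA of cardiac and skeletal muscle, 31.8%. miR-1 also led in oesophagus with 27.9% (27.9–28.0%), ahead of miR-143 with 22.9% and miR-378 with 18.3%. Mouse oesophagus has striated muscle along its wall. In brain, let-7f, let-7c and let-7a came first with 26.7%, 16.7% and 9.53%, and the 8 names from let-7a to let-7i together held 64.4% of the reads. In cerebellum, miR-378 held 34.5%, let-7c 19.2% and let-7b 8.57%.

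miR-143, a miRNA known from smooth muscle and other mesenchymal cells, was the most abundant name in 7 libraries. Its share was 98.7% (98.7–98.7%) in the library labelled colon, 87.1% (87.1–87.1%) in ovary, 70.2% in stomach, 61.1% in lung, 56.8% in the library labelled uterus, 53.6% in small intestine and 51.8% in spleen. It was second in kidney, with 29.6% behind 30.1% for miR-378, and held 4.01% in pancreas, 4.53% in cerebellum, 6.14% in liver and 6.32% in brain. Reads other than miR-143 numbered 86545 in the colon library and 292350 in ovary. RPM values of other names lie low in these libraries for that reason, and folds against them are also given with totals without miR-143. Small intestine had miR-215 in second place with 17.0%, and the library labelled uterus had miR-378 with 20.9% and miR-215 with 5.11%.

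**Figure D1:**
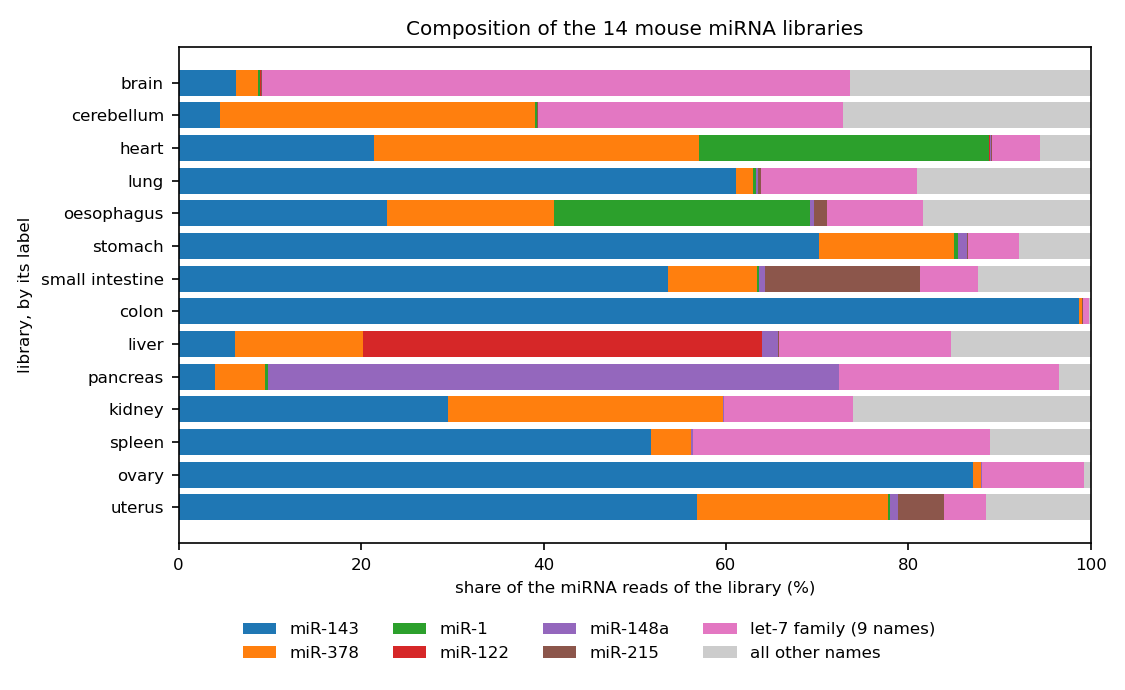
Composition of the 14 libraries, each bar summing to 100% of its miRNA reads on the horizontal axis, with 1 bar per library and colours for 6 miRNAs, the let-7 family and all other names. miR-143 fills 98.7% of the bar labelled colon and 87.1% of that of ovary, miR-122 fills 43.7% of liver and miR-148a 62.6% of pancreas.

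Some names were present in every tissue. At 100 RPM or more in all 14 libraries there were 12, namely miR-143, miR-378, miR-21, miR-26a, miR-101a, miR-148a and let-7a, let-7b, let-7c, let-7f, let-7g and let-7i. At 10 RPM or more in all 14 there were 43. The library labelled colon limits both counts, since miR-143 held 98.7% of its reads and only 57 names reached 10 RPM there. With at least 1 read in all 14 libraries there were 162 names. miR-143 had the lowest specificity index of the 12 (tau 0.105), and miR-148a the highest (0.432), with 625591 RPM in pancreas. miR-26a and miR-101a were named after their values were seen, because this set is given in full.

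The tissue-enriched rule called 44 miRNAs, of which brain held 19, cerebellum 10, pancreas 5, spleen 3, heart 2, oesophagus 2, and lung, small intestine and liver 1 each. The other 5 libraries held none. In brain, miR-137 reached 1407 RPM, 47.8-fold (42.2–54.4) above the next library, and miR-380-3p 141 RPM, 51.8-fold (34.3–82.2) above stomach. miR-153 stood 30.8-fold (18.3–56.4) and miR-369-5p 26.0-fold (17.9–39.5) above the second tissue. miR-128, miR-132 and miR-383, all on the neural list, were 5.02-fold, 5.53-fold and 9.23-fold higher in brain than in cerebellum. Cerebellum led for miR-129-5p with 15018 RPM, 16.2-fold (15.7–16.7) above brain, and for the star names miR-204* (20.5-fold), miR-127* (10.9-fold) and let-7d* (7.93-fold).

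Outside the nervous system, miR-122 reached 437407 RPM in liver, 1083-fold (1049–1119) above kidney. Pancreas led for miR-217 at 2967 RPM, 38.7-fold (31.2–48.6) above cerebellum, for miR-148a by 35.1-fold over liver, and for miR-216b and miR-216a by 29.8-fold (13.2–83.2) and 10.5-fold (8.05–14.0). miR-216a, miR-216b and miR-217 are known acinar miRNAs, and the reference annotation places the gene of miR-217 next to that of miR-216a. Heart led for miR-499, a miRNA encoded inside a myosin gene, at 102 RPM and for miR-133a at 1530 RPM, 6.49-fold (6.12–6.89) above oesophagus. Oesophagus led for miR-206, known from skeletal muscle, at 42616 RPM, 5.97-fold (5.84–6.10) above cerebellum, and for miR-483. Spleen led for miR-142-3p, a miRNA of blood cells, at 10642 RPM (13.5-fold), and for miR-155 and miR-150, lymphocyte miRNAs, by 8.10-fold and 5.48-fold. Lung led for miR-542-3p by 5.06-fold, and small intestine for miR-215*, 17.0-fold (15.2–18.9) above the library labelled uterus.

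Counts per tissue depended on the scaling. With median-of-ratios factors 39 names were called, 26 of them shared with the 44, and brain had 9, heart 6, pancreas 8, ovary 3 and lung and oesophagus 0. With totals without the 5 most abundant names there were 61, of which 34 were shared. With totals without miR-143 there were 40, of which 34 were shared, and brain had 16 and cerebellum 6.

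**Figure D2:**
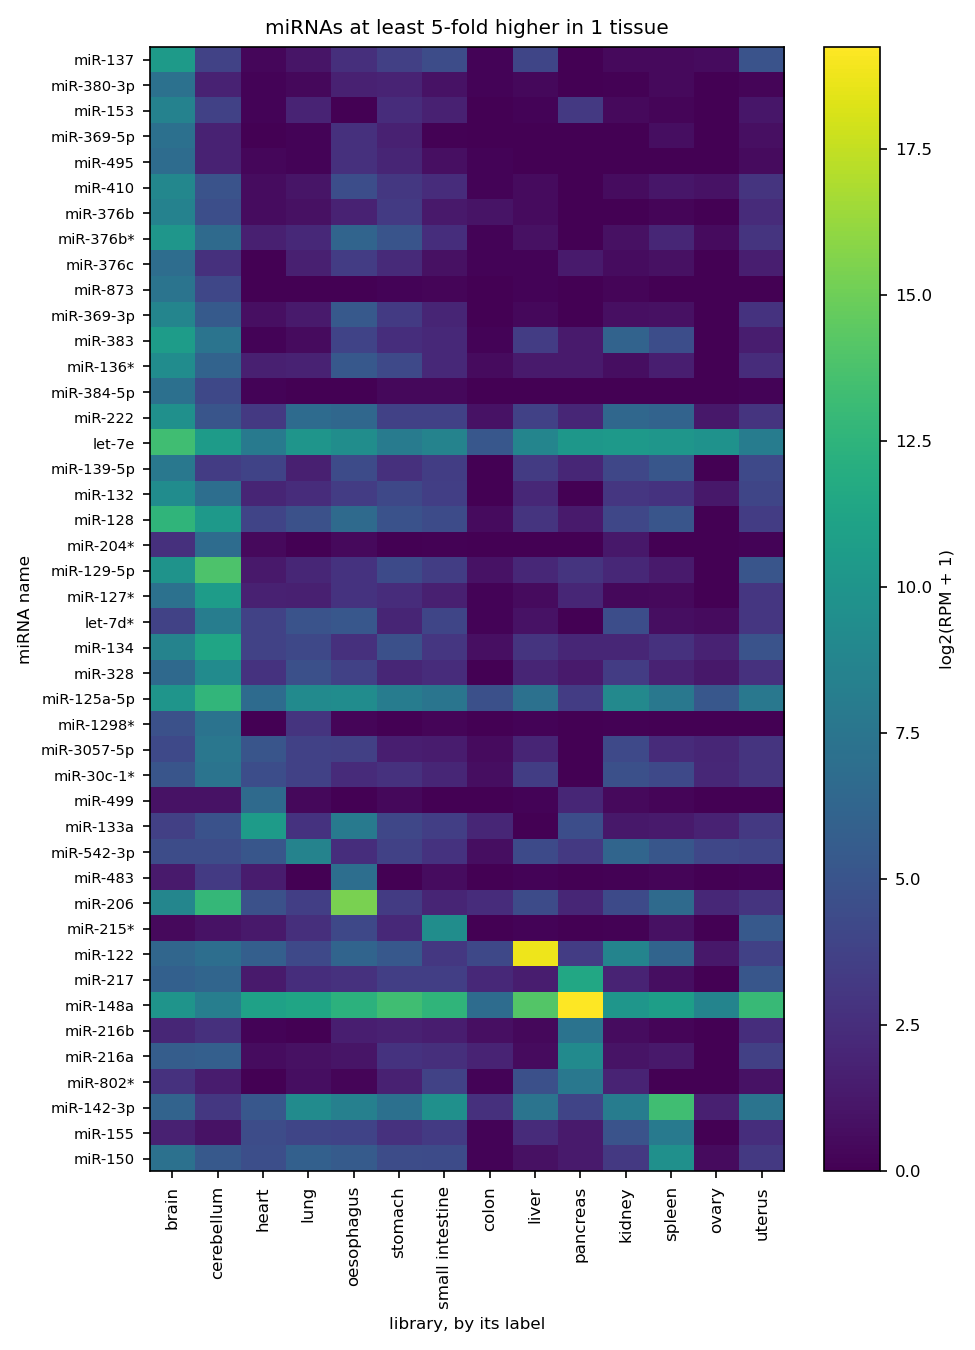
Heat map of the 44 tissue-enriched miRNAs, with names on the vertical axis grouped by their highest tissue, the 14 libraries on the horizontal axis and colour for log2(RPM + 1). The first 19 names peak in brain and the next 10 in cerebellum, and the brightest cells are miR-148a in pancreas (625591 RPM) and miR-122 in liver (437407 RPM).

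The specificity index covered 418 names at 10 RPM or more in some library, and its median was 0.640. Of these, 89 (21.3%) reached 0.85, 49 with their highest value in brain and 24 in cerebellum. The set depended on the scaling, since 63 names were specific with median-of-ratios factors (54 shared with the 89), 68 with totals without miR-143 (58 shared) and 80 with totals without the 5 most abundant names (39 shared). Among list members, miR-122* (the star arm of the miR-122 hairpin) had tau 1 in liver, the only tissue with reads, miR-208a-3p (encoded in a cardiac myosin gene) 0.963 in heart, miR-329 (Dlk1-Dio3 cluster) 0.953 in brain and miR-449a (multiciliated cells) 0.952 in lung. These names were scarce, with 11.3, 30.4, 28.6 and 14.0 RPM in their highest tissue.

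Of the 17 lists with an expected tissue, 16 had their highest median in such a tissue with totals. The score was 15 of 17 with median-of-ratios factors and with totals without miR-143. Some lists had several expected tissues, any of which counted, and no rate expected by chance was computed. Colon was among the expected tissues of the intestinal and miR-200 lists. Both counted as hits, although their medians were lowest in the library labelled colon (−5.59 and −5.36). All 15 neural members lay above the median of the other tissues in both brain and cerebellum. Their median difference was 8.05 (log2) in brain and 5.76 in cerebellum, above 100% and 99.98% of random lists. miR-9 reached 62282 RPM in brain and 14705 in cerebellum, against 0.150 RPM in the library labelled colon and 312 in oesophagus. miR-124 was higher in cerebellum (20760 RPM) than in brain (5506 RPM). The neural list also had a median of 1.65 in stomach, above 99.82% of random lists, at 443 RPM summed over its members.

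The Dlk1-Dio3 cluster is a large group of miRNAs expressed from the maternal chromosome. All 41 listed members lay above the median of the other tissues in brain (median 5.46) and 38 did in cerebellum (3.29), both above 100% of random lists. These medians were 4.04 and 2.34 with median-of-ratios factors, and 2.77 and 1.24 with a pseudocount of 10 RPM. miR-127 reached 49447 RPM in cerebellum and 12234 in brain, miR-541 reached 10731 and 5010, and miR-379 2695 and 12873. The summed level of the cluster was 80660 RPM in cerebellum and 47219 RPM in brain. Oesophagus came next with totals, with 39 members above and a median of 1.63, but stomach did under the 3 other scalings, at 1.92 with totals without miR-143. The let-7 family was highest in brain (median 2.82, 9 of 9 members above) and then in spleen (1.64), but under the 3 other scalings its highest median was in ovary, at 2.17 with totals without miR-143.

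The 7 striated muscle members had their highest median in heart, at 6.21 (above 100% of random lists), and the second in oesophagus at 4.01 (99.99%), although with median-of-ratios factors pancreas (2.58) came before oesophagus (2.33). Both tissues held about the same summed level, 320188 RPM in heart and 322362 in oesophagus. They differed in members, since miR-208a-3p, miR-208b and miR-499 were highest in heart while miR-206 stood at 26.0 RPM there. In liver these 7 summed to 59.9 RPM. The median of the list in the library labelled colon was −0.69 with totals and 1.40 with totals without miR-143.

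The hepatocyte list had its highest median in liver (3.63) and the pancreatic list in pancreas (7.20, 5 of 6 members above). miR-802, listed for hepatocytes, was highest in pancreas at 291 RPM, against 43.3 RPM in liver. The white blood cell list was highest in spleen (5.13, 7 of 7 above) and then in lung (2.14). The red blood cell list was highest in spleen (4.32) and lung (3.49), and miR-451 reached 658 RPM in spleen, 573 in kidney and 440 in lung. It stood at 0.441 RPM in ovary and had no reads in pancreas. The miR-17~92 and paralogous clusters, known from dividing cells, were highest in spleen (2.23, 12 of 12 above), followed by small intestine (2.09), and small intestine led under 2 of the 3 other scalings.

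Epithelial groups separated the organs. The 5 miR-200 family members were highest in kidney (6.11), small intestine (5.66), the library labelled uterus (5.63), stomach (4.88) and oesophagus (4.65), and all 5 were below the other tissues in brain, cerebellum, heart, spleen and ovary. They were also below in the library labelled colon, with the lowest median of all (−5.36), which was 0.50 with totals without miR-143. With totals without miR-143 the order changed to the library labelled uterus (4.83), small intestine (4.74), stomach (4.17) and kidney (4.02). Of the squamous pair, miR-203 reached 19548 RPM in oesophagus and 4391 in stomach, and miR-205 903 and 210.4 RPM. The 4 intestinal members were highest in small intestine (6.02), then in the library labelled uterus (4.49) and liver (4.45), and all 4 were below the other tissues in the library labelled colon (−5.59 with totals, −0.18 with totals without miR-143). The 4 names of the smooth muscle list had their highest median in stomach (2.78). Its value in the library labelled colon was −1.58 with totals but 3.20 with totals without miR-143, the highest of the 14. miR-143 was left out of the total only and stayed among the 4 names, so this median includes its excess.

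Kidney led for the renal list (3.43, 9 of 9 above), with miR-30a at 35191 RPM and miR-30e at 25252. With median-of-ratios factors the renal list stood at 1.89 in kidney, close to liver at 1.72. Kidney also led for the Hox cluster miRNAs (5.97, 5 of 5 above), which lie among the genes that pattern the body axis. miR-10a reached 23048 RPM and miR-196b 4706 RPM there, followed by 12584 and 1569 RPM in the library labelled uterus. The Hox list stood at −0.22 in the library labelled colon with totals and at 5.10 with totals without miR-143. With median-of-ratios factors, kidney (3.49), the library labelled uterus (3.48) and that labelled colon (3.47) were nearly level for this list. Lung led for endothelial miR-126-3p (27888 RPM) and for the multiciliated list (4.25), in which miR-34c held 5573 RPM in lung and 1987 in brain.

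The gonadal list was the exception to its expected tissue with totals. Of its 17 members 10 had reads, and only miR-202-3p (6.17 RPM) and miR-202-5p (2.65 RPM) exceeded 1 RPM in ovary. The miR-183 cluster of sensory and secretory cells, with no tissue fixed in advance, was highest in the library labelled uterus (2.37) and small intestine (2.05), though pancreas led with median-of-ratios factors. The 10 pluripotency miRNAs, expected near 0 in adult tissue, had 1 read in all 14 libraries together.

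Similarity between profiles was measured across names, which are not independent replicates. The median rho of the 91 pairs was 0.773. Brain and cerebellum had 0.785 with each other and at most 0.614 with any other library (brain with stomach), and the lowest rho of all was 0.428, between brain and kidney. The highest was 0.933, between small intestine and the library labelled uterus, followed by 0.908 between stomach and the library labelled uterus. Lung was nearest to kidney (0.894), heart to lung (0.865) and oesophagus to stomach (0.886). The library labelled colon was nearest to ovary (0.825), and with miR-143 left out and equal depth it was nearest to stomach (0.755) and lung (0.755).

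**Figure D3:**
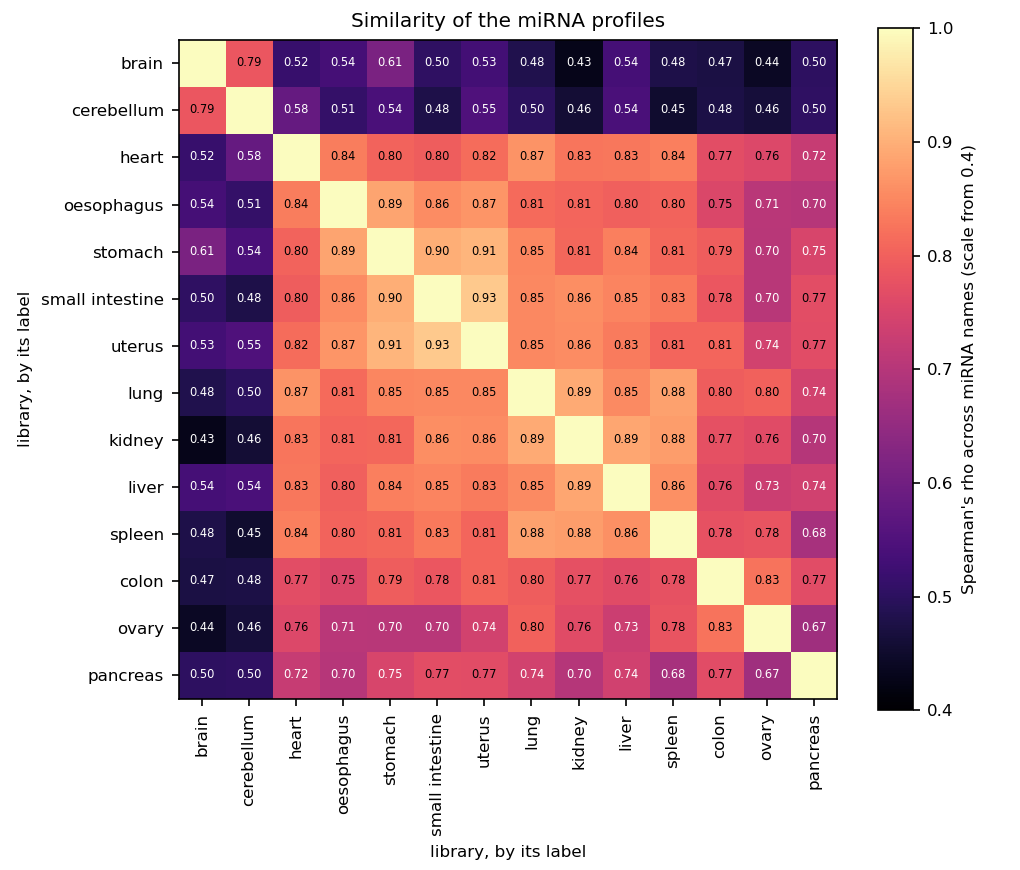
Matrix of Spearman's rho across miRNA names for the 91 pairs of libraries, with the libraries on both axes, colour from 0.4 to 1 and the value written in each cell. Brain and cerebellum form a block at 0.785, and the cell of small intestine with the library labelled uterus is the highest, at 0.933.

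Brain against cerebellum asks how a region of the nervous system differs from the sample labelled brain. By the rule of size, 48 names were higher in brain and 29 in cerebellum, and 32 against 26 with median-of-ratios factors, 66 against 44 with totals without the 5 most abundant names and 49 against 28 with totals without miR-143. miR-137, miR-153 and miR-222 were higher in brain by 106-fold (64.5–190.2), 30.8-fold (18.3–56.4) and 24.5-fold (17.8–34.6), and miR-708 and miR-31 by 78.9-fold and 64.2-fold. Several Dlk1-Dio3 names were also higher in brain, including miR-380-3p (53.4-fold, 18.2–259.6), miR-369-5p (52.5-fold, 17.9–255) and miR-495 (42.3-fold, 14.4–205), each with 3 reads in cerebellum. Other members of this cluster were higher in cerebellum, among them miR-127* (10.9-fold, 9.98–11.8), miR-134 (6.73-fold, 6.36–7.12) and miR-127 (4.04-fold, 3.996–4.088). Cerebellum was higher for miR-744 (61.9-fold, 51.8–74.4), miR-423-5p (30.0-fold), miR-320 (18.1-fold), miR-129-5p (16.2-fold), miR-206 (15.6-fold, 14.9–16.3) and miR-378 (14.7-fold, 14.6–14.8). Of these, miR-206 is known from skeletal muscle, and cerebellum also came second after pancreas for the acinar names miR-217 (76.7 RPM) and miR-216a (55.5 RPM). The source of such reads in the cerebellum library was not tested. Names higher in cerebellum came from hairpins with a median GC content of 52.7%, against 45.2% for those higher in brain.

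Small intestine was set against the library labelled colon as a pair of intestinal segments per the labels. With totals, 88 names were higher in small intestine and 0 in the colon library. The split was 26 against 15 with median-of-ratios factors, 42 against 60 with totals without the 5 most abundant names and 31 against 35 with totals without miR-143. miR-215, miR-194 and miR-192, which share 2 clusters and are on the intestinal list, were higher in small intestine by 37739-fold (26436–55934), 9729-fold (4722–24199) and 1680-fold (1416–2010), with 30, 7 and 131 reads in the colon library. With totals without miR-143 the folds were 1055, 272 and 47.0. miR-215* had 6408 reads in small intestine and 0 in the colon library, at least 1526-fold apart on a floor of 3 reads, or at least 42.7-fold with totals without miR-143. The miR-200 family was also higher in small intestine, miR-200c by 752-fold (592–970) and miR-200b by 680-fold (461–1051), or 21.0-fold and 19.0-fold with totals without miR-143.

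**Figure D4:**
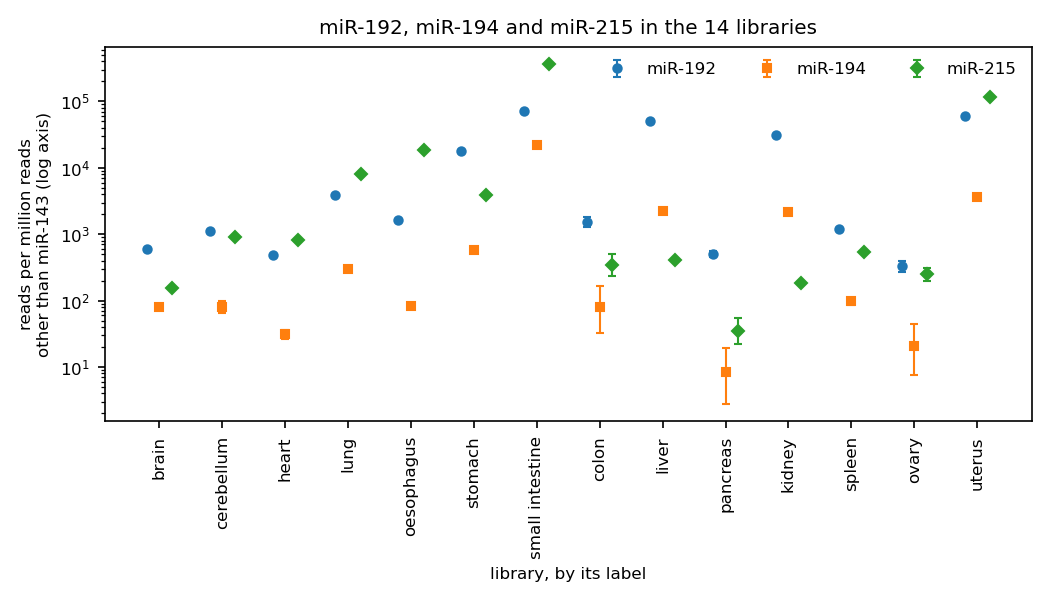
miR-192, miR-194 and miR-215 in the 14 libraries, as reads per 1000000 reads other than miR-143 on a log axis, with points for the value and bars for the 95% exact Poisson interval. miR-215 reaches 365682 in small intestine and 118373 in the library labelled uterus, against 347 in the library labelled colon.

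Oesophagus against stomach compares the upper digestive tract. With totals, 33 names were higher in oesophagus and 4 in stomach, a split of 7 against 8 with median-of-ratios factors, 20 against 27 with totals without the 5 most abundant names and 11 against 21 with totals without miR-143. Muscle names were higher in oesophagus with totals, with median-of-ratios factors and with totals without miR-143, miR-206 by 4731-fold (3780–6005), miR-1 by 66.9-fold (66.2–67.6) and miR-133a by 14.6-fold (12.2–17.6), or 1827, 25.8 and 5.64 with the last of these. miR-483 had 644 reads in oesophagus and 0 in stomach, at least 345-fold apart, or at least 133-fold with totals without miR-143. The 4 names higher in stomach were miR-375, a miRNA of endocrine cells, by 74.98-fold (41.8–150.6), miR-184 by 21.5-fold, miR-31 by 7.63-fold and miR-192 by 4.36-fold, or 194, 55.8, 19.8 and 11.3 with totals without miR-143. miR-215 went the other way from miR-192, 12.3-fold (12.01–12.54) higher in oesophagus, or 4.74-fold with totals without miR-143.

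Ovary was set against the library labelled uterus as the female reproductive tract per the labels. With totals, 2 names were higher in ovary, miR-322* (15.9-fold, 11.8–21.8) and miR-34c (8.71-fold, 7.65–9.93), or 53.2-fold and 29.1-fold with totals without miR-143, and 63 in the uterus library. The split was 20 against 20 with median-of-ratios factors, 24 against 65 with totals without the 5 most abundant names and 14 against 50 with totals without miR-143. Intestinal and epithelial names led in the uterus library, miR-215 by 1587-fold (1262–2024), miR-192 by 617-fold (505–762), miR-194 by 584-fold (268–1591) and miR-200c by 347-fold (246–507). With totals without miR-143 these folds were 474, 184, 174 and 104. miR-375 had 2988 reads in the uterus library and 0 in ovary, at least 259.6-fold apart, or at least 77.6-fold with totals without miR-143. The Hox cluster name miR-196b was 712-fold (305–2192) higher in the uterus library, or 213-fold with totals without miR-143.

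Brain against liver served as a scale for the other pairs. With totals, 97 names were higher in brain and 12 in liver, and 54 against 24 with median-of-ratios factors. Brain was higher for miR-434-3p (1725-fold, 1185–2618), miR-9 (1057-fold, 955–1172), miR-128 (1009-fold) and miR-124 (573-fold). Liver was higher for miR-122 (5322-fold, 4846–5858), miR-10a (259-fold, 195–353), miR-192 (86.3-fold), miR-194 (28.5-fold), miR-148a (17.6-fold) and miR-21 (10.98-fold).

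There were 407 pairs of names for the arms of a hairpin, and 126 pairs could be compared across libraries. The more abundant arm differed between libraries in 4 of them. For miR-151 the 3p arm led in 9 of 12 libraries, with 5020 RPM against 103 RPM for the 5p arm in cerebellum, while in brain the 5p arm led with 1233 against 552 RPM. miR-142-3p led over miR-142-5p in 7 libraries, and the 5p arm led in 3, among them pancreas with 94.8 against 14.5 RPM. miR-423-5p led in 8 libraries, and in spleen the 3p arm led with 114 against 45.1 RPM. For miR-342 the 3p arm led in brain (1196 against 181 RPM) and the 5p arm in cerebellum (179.8 against 128 RPM). The widest ranges of arm ratio were those of let-7d (9.82 on the log2 scale), miR-148a (8.73), miR-143 (8.23), miR-122 (8.18), miR-29a (6.84) and miR-151 (6.75). Cerebellum was the low end for all of these but miR-143, so most of these ranges rest on a single library. A possible GC bias between the cerebellum and brain libraries is described below. That comparison used hairpin GC, which both arms share, so it does not address arm ratios. For miR-122 and miR-29a the star arm had 0 reads at an end of the range, and for let-7d and miR-143 it had 3 and 2 reads there, so these ranges depend on the pseudocount and on depth. In 13 hairpins the star or 3p arm led in every library compared, and 5 of these were star names, miR-664*, miR-140*, miR-28*, miR-144* and miR-376b*, identified after their values were seen.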

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

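Totals without miR-143, runs without the libraries labelled colon, ovary, pancreas or uterus, and the comparison with miR-143 left out at equal depth were chosen after the results were seen, and the other settings before. Of the alternative values of the main counts and medians, 45 stayed within their tolerance (1.5-fold for counts, 0.05 for rho) and 24 moved. The tolerance for counts judges their size only, so a count could stay within it while its names or its direction changed. Specific names by tau stayed within it at 80 with totals without the 5 most abundant names, although only 39 were shared. Small intestine against the colon library stayed within it at 66 with totals without miR-143, although its direction changed. Of the list medians, 27 moved by at most 1 (log2) and 18 by more.

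A minimum in the higher library of 0 or 1000 RPM, in place of 100 RPM, changed every count by construction. Tissue-enriched names were 89 and 15, names apart between brain and cerebellum 167 and 34, between small intestine and the colon library 215 and 31, between oesophagus and stomach 73 and 15, between ovary and the uterus library 191 and 20, and between brain and liver 301 and 40. Enrichment of 10-fold left 23 names. Specific names by tau were 152 with a pseudocount of 10 RPM, 287 on linear values and 369 with no minimum. Detection at 1 RPM or 100 RPM gave medians of 339.5 and 91 names. Arms differed in 2 hairpins at 1000 RPM.

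Median-of-ratios factors gave 41 names apart between small intestine and the colon library, 15 between oesophagus and stomach and 40 between ovary and the uterus library. Totals without the 5 most abundant names gave 169 between brain and liver. The median rho was 0.684 at equal depth without miR-143. The side with more names changed for small intestine and the colon library without miR-143 (31 against 35) and without the 5 most abundant names (42 against 60), and for oesophagus and stomach under all 3 other scalings.

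Without the libraries labelled colon and uterus 47 names were tissue-enriched, including all 44, and without those labelled colon, ovary and pancreas 39 remained. Without cerebellum there were 64, with 37 of the 44. No paired analysis was possible because each tissue has 1 library and no test was run.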

Other observations

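miR-215 and miR-192 have nearly the same sequence, yet their ratio differed widely between tissues. It was 11.4 (11.1–11.7) in oesophagus, 5.14 in small intestine, 2.02 in lung and 1.95 in the library labelled uterus, against 0.213 in stomach, 0.00799 in liver and 0.00602 in kidney. miR-215 reached 14117 RPM in oesophagus, 0.0832 of its small intestine level, where miR-194 stood at 0.00625 of its own. miR-206, a skeletal muscle miRNA, was present in cerebellum at 7143 RPM with miR-1 at 2045 RPM, while in heart miR-206 was at 26.0 RPM and miR-1 at 318375 RPM. miR-34c stood at 5573 RPM in lung, 1987 in brain and 334 in ovary, and at 38.4 in the library labelled uterus.

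Of the tests that follow, the label exchange test was written before its result was seen, and all others were chosen or reworded afterwards. The test for fewer kinds of molecules had first been written for the libraries labelled colon and ovary together, was undecided in that form, and was split by library after its result was seen. The threshold for GC content was written after its rho was seen. Tests of small intestine RNA and of shared reads for miR-215 in oesophagus were also run, and only their values are given above, with no verdict drawn from them.

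Intestinal miRNAs stood in the library labelled uterus and hardly in that labelled colon. Not all of them are confined to intestine, since miR-192 was highest in liver (48346.5 RPM) and reached 21819 RPM in kidney. miR-194 stood at 1545 RPM in the uterus library, against 2124 in liver and 1531 in kidney. miR-215 stood at 51092 RPM in the uterus library, against 386 in liver and 131 in kidney. Loss of reads to miR-143 in the colon library is argued against. Per 1000000 other reads, miR-192, miR-194 and miR-215 together were still 94.0 times higher in the uterus library (182504 against 1941). In the uterus library, fractions of the small intestine level ran from 0.00927 for miR-31 to 0.792 for miR-192, bounds at least 62.1-fold apart. This argues against carry-over of small intestine RNA at a common fraction as the only source. Yet miR-215 and miR-215*, arms of the same hairpin, also differed (0.301 and 0.0590). Part of this spread can therefore arise between strands, and carry-over of intestinal RNA as part of the pattern stays open. With miR-143 left out and at equal depth, rho with small intestine was higher for the uterus library than for the colon library by 0.0713 (0.0441–0.101 over 20 draws), and by 0.0605 (0.0309–0.0912) with 18 intestinal and miR-200 family names left out as well. Without these 18 the uterus library was no closer to small intestine (0.776) than to stomach (0.779), and the colon library had 0.715 and 0.748, so this comparison does not single out small intestine. An exchange of these labels may be involved, and a true difference between the tissues, or a wrong label of another kind, stays open and untested.

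miR-143 took 98.7% of the reads in the library labelled colon and 87.1% in ovary. The cluster partner of miR-143, miR-145, argues against more smooth muscle RNA as the whole cause. It stood at 924 per 1000000 other reads in the colon library and 37.6 in ovary, below 4709 in stomach. For the colon library miR-145* goes the other way, being higher there (2045) than in stomach (539.9). Yet miR-145* also stood above miR-145 in the colon library, whereas miR-145 led in all 9 libraries where these arms were compared. The smooth muscle list had its highest median in the colon library under the 3 other scalings, at 3.20 with totals without miR-143. miR-143 is 1 of its 4 names, so this median cannot separate smooth muscle RNA from the excess of miR-143 itself. More smooth muscle RNA as part of the cause in the colon library stays open. There were 598730 miR-143 reads per miR-143* read in the colon library and 987434 in ovary (11 and 2 star reads), against 1553 to 16276 in the other libraries with star reads. At equal depth, the colon library showed 282 names, inside the range of 175.15 (liver) to 359.3 (brain) with a median of 267.7 in the 11 libraries apart from pancreas (134.25), which gives no sign of fewer kinds of molecules but leaves them open beside a rich profile, while for ovary they cannot be told apart from a sparse profile, with 181.7 names. A bias in amplification or carry-over of a miR-143 product could leave such ratios and was not tested, nor was a biological explanation.

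Names apart between brain and cerebellum differed in GC content. Across 339 names, hairpin GC correlated with the log2 ratio of cerebellum to brain at rho 0.323, the second largest in size of the 91 pairs after heart and liver (−0.344), against a median size of 0.0921. With a straight line on hairpin GC taken off, 64 of the 77 names stayed at least 4-fold apart, 45 of 48 for brain and 19 of 29 for cerebellum. This argues against a linear effect of hairpin GC as the whole cause. Both arms of a hairpin share its GC value, so GC content of the sequenced strand was not tested. With brain thinned to the cerebellum total, at least 74 of the 77 stayed apart, so the calls do not need the extra reads of brain. This outcome was close to fixed in advance. Thinning keeps the expected RPM, and each called name had at least 100 RPM in the higher library. It therefore says little about the cause. Thinning brain leaves low counts in cerebellum as they are, so their counting error was not tested this way. A GC bias in library preparation may therefore account for part of the difference, and a difference of tissue stays open beside it.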
